A study of Homo sapiens with 12 samples.

How the data were processed

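VDR ChIP-seq was carried out in 12 libraries of THP-1 cells, in 4 groups of 3 (solvent or 10 nM 1,25D, for 40 min or 4 h). The authors deposited a table of raw counts per window, 1 column per library, with windows of 150 bp that start 50 bp apart; the values are whole numbers and their totals differ between libraries. Reads were processed with STAR and SAMtools and the builds hg38 and GRCh38.p14 are named, per the submitters' processing notes. Which program counted the reads, how duplicates and reads with several matches were treated, and how the listed windows were chosen are not given in the sources used here. No input or control antibody library was used here, so background cannot be subtracted, and a window listed in the table need not be bound. Because windows overlap, a read can be counted in several rows.

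Windows up to 100 bp apart were merged, and merged stretches were split at 5000 bp, which gave 19169 regions. Each region was represented by its window with the highest count summed over the 12 libraries, chosen without regard to group. The merging rule was set once the table had been seen. Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling on the totals of the table, the filterByExpr filter by group (8736 regions kept), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. All 12 libraries entered a single fit of the 4 groups. Log2 fold changes are given with standard errors (SE), and levels as CPM (counts scaled to the TMM-adjusted table total). Each SE was derived from the edgeR test, as the absolute log2 fold change divided by the square root of the F statistic. It therefore rests on a spread estimated over all 12 libraries and shared in part across regions. Replicate number was not in the fit. TMM factors ranged from 0.767 to 1.19.

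Regions were assigned to the nearest protein-coding gene of a gene table on GRCh38.p14, at most 100 kb away and 0 bp if inside it, which gave a gene to 16399 regions (85.5%). The table gives no strand, so distance to a gene end replaced the planned distance to a transcription start site. No genome sequence was used here, so the planned search for VDR response elements was not made. Exons, introns and UTRs were likewise not assigned.

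The tests, gene lists, a first set of alternatives and the rule for named genes were fixed before the data were examined. That rule took, at each time, the 10 called regions with the largest rise, the 5 higher regions with the highest mean count and the 5 with the largest fall. Each needed a mean of at least 20 counts and groups that did not overlap, with 1 region per gene. It also took 12 vitamin D targets whatever their result and up to 4 members of each other list with the smallest p at 4 h. Of the 5 falls that this rule took at 40 min, 1 is not reported here. The 12 lists were monocyte vitamin D targets, transcription factors under vitamin D, vitamin D metabolism and receptor, innate immune recognition, cytokines and chemokines, antigen presentation, cell cycle and growth, sugar and lipid metabolism, calcium transport and bone, housekeeping, lymphocyte markers, and liver and neuron markers. Each gene was represented by its region with the highest mean count. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01.

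The scripts were tested on simulated counts for the 8736 regions. At 4 h, 84.8% of 4-fold and 8.82% of 2-fold rises were recovered, and 18.2% of 4-fold falls. At 40 min these were 66.7%, 5.88% and 15.2%. Each share rests on 33 or 34 changed regions in a single simulated data set per comparison. Of the calls in these simulations, 3 of 41 were false at 4 h (7.32%) and 2 of 31 at 40 min (6.45%). No 2 replicates agreed within sampling noise (chi-square per degree of freedom from 1.78 to 3.37), so all were counted. With 3 libraries against 3, a permutation test cannot go below p = 0.1, so p-values rest on the edgeR model across regions.

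Set beforehand for comparison were other scalings (RLE, total counts, regions with lower counts), other filters, DESeq2 1.42.0, an adjusted p under 0.01, a test against 1.5-fold, the replicate number as a block, only the groups compared, and each library left out. Chosen after seeing the data were scaling to the dense stretch of chromosome 1, leaving its regions out, testing all windows with Simes' method, a merging gap of 500 bp, leaving out all replicate 2 libraries, and thinning the 4 h libraries. The stretch was taken as the bins of 50 kb with at least 500 of 1000 possible windows. The filterByExpr filter was applied anew in each new edgeR fit that used it. Fits without 1 library therefore tested 9518 to 12866 regions, against 8736 in the main fit. A call lost in such a fit can reflect the library or the changed set of tested regions. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.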

Results

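VDR, the nuclear receptor through which vitamin D acts, was mapped by ChIP-seq in THP-1 cells, a human monocytic leukaemia line. Cells received 10 nM 1,25(OH)2D3 (1,25D), the active form of vitamin D, or 0.1% ethanol as solvent, for 40 min or 4 h. Each of the 4 groups held 3 libraries, which the titles call ChIP replicates and the submitters' treatment notes call biological replicates. Summed over the 191638 windows of 150 bp in the deposited table, the libraries held between 1258218 counts (1,25D 40 min replicate 1) and 3650579 counts (1,25D 4 h replicate 2). Neighbouring windows overlap, so these totals exceed the number of reads behind them. The windows were merged into 19169 regions, of which 8736 had enough counts to be tested. The first principal component, with 29.95% of the variance, placed all 6 solvent libraries on one side of 0 and all 6 1,25D libraries on the other. The second, with 16.38%, set solvent 40 min replicate 2 (-82.84) apart from the other libraries (-6.62 to 29.16). That library also had the highest share of tested regions without a count, 8.29%.

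A stretch of chromosome 1 from 39500001 to 43800000 (GRCh38.p14) held 72450 of the windows, or 37.8%. It took 49.3% to 61.6% of the counts in solvent libraries and 37.1% to 48.8% in 1,25D libraries. Its 1067 tested regions had a median log2 fold change of -0.59 at both times, against 0.09 at 40 min and 0.06 at 4 h for regions elsewhere.

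**Figure D1:**
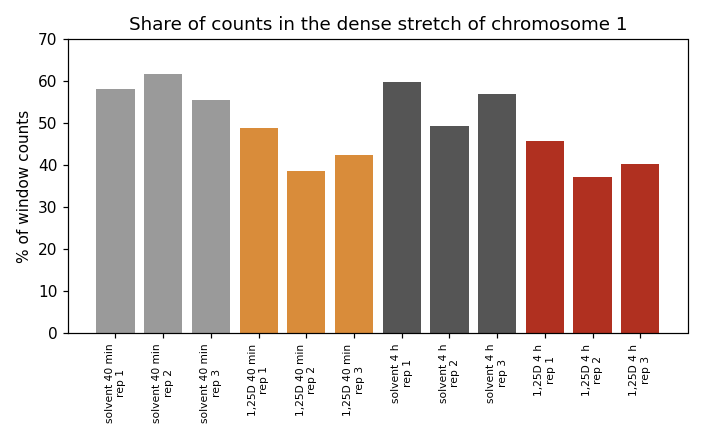
Percentage of each library's window counts that fell in the densely covered stretch of chromosome 1, as 1 bar per library and an axis from 0. The 6 solvent libraries lay between 49.3% and 61.6% and the 6 libraries with 1,25D between 37.1% and 48.8%.

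The first comparison asked where VDR binding differed after 40 min of 1,25D. More regions had higher than lower counts with 1,25D: 492 were higher and 58 were lower. Falls were harder to detect: in simulated data, 66.7% of 4-fold rises and 15.2% of 4-fold falls were recovered at 40 min. In a separate fit of only the 1478 regions with a mean of at least 20 counts, the split was 260 and 205. With only the groups compared it was 384 and 171 of 2935 tested regions, because the filter was applied anew. With scaling to the dense stretch it was 1163 and 12. The higher regions had a median log2 fold change of 1.80, and 27 of them rose at least 8-fold. The largest rise among regions with a mean of at least 20 counts lay 590 bp from IGFBP7, which encodes a secreted growth factor-binding protein (chromosome 4, 57110351 to 57111550). Its scaled counts (CPM) went from 0.971 ± 1.24 to 33.2 ± 8.26 (SD, n = 3 each). The strongest site by count that also rose strongly had no protein-coding gene within 100 kb (chromosome 1, 221957051 to 221959200). It went from 28.1 ± 1.55 to 250 ± 69.7 CPM (SD, n = 3 each).

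By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the IGFBP7 region rose by a log2 fold change of 5.07 ± 0.57 (SE, adjusted p = 2.83e-11). The chromosome 1 site rose by 3.16 ± 0.27 (edgeR, adjusted p = 2.14e-17). Under the same count limit, the next largest rises near genes were at NINJ1 (3.90 ± 0.57), a cell-surface adhesion protein, SPRY4 (3.77 ± 0.70), an inhibitor of growth factor signalling, and COL23A1 (3.57 ± 0.49), a membrane collagen. LSM3, part of the RNA splicing machinery, followed with 3.29 ± 0.50, and GZMB, the protease granzyme B, with 3.07 ± 0.49. SPRY4 lay 63704 bp and GZMB 26235 bp from its region, so the nearest gene names a place and not a target. Among regions with a mean of at least 20 counts, rises above 3 also stood at 3 further sites with no gene within 100 kb, on chromosome 17 (3.99 ± 0.68), chromosome 2 (3.13 ± 0.37) and chromosome 9 (3.11 ± 0.51). Among the regions with the most counts, smaller rises were called at TNR (1.12 ± 0.24), CHD7 (0.85 ± 0.22), CAP1 (0.80 ± 0.24, in the dense stretch) and SP100 (0.78 ± 0.24). The calls at CHD7, CAP1 and SP100 were each lost without solvent 40 min replicate 1. CHD7 and SP100 were also lost without solvent 40 min replicate 2, CAP1 and SP100 without 1,25D 40 min replicate 2, and SP100 without 1,25D 40 min replicate 3. Without solvent 40 min replicate 1, 299 regions were higher. That fit tested 12588 regions, against 8736, because the filter was applied anew.

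The 58 regions lower at 40 min had a median log2 fold change of -2.05, and 26 of them (44.8%) lay in the dense stretch. Of the named falls, RIMS3 (-1.17 ± 0.34), PPT1 (-1.15 ± 0.36), a lysosomal enzyme gene, and ZMPSTE24 (-1.14 ± 0.33), the prelamin protease gene, were all in the stretch. AHCTF1, a nuclear pore protein gene (-1.32 ± 0.36), lay outside it, 21173 bp from its region. That region, at 246817751, lay in the closely spaced part toward the end of chromosome 1. These 4 calls (edgeR, SE) were lost when libraries were scaled to the stretch itself, a setting chosen after seeing the data, and all 4 were also lost without 1,25D 40 min replicate 2. Under that scaling 12 regions were lower. In fits without 1 library, the number of lower calls ranged from 14 without 1,25D 40 min replicate 2 to 74 without solvent 4 h replicate 2.

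The second comparison asked the same after 4 h. Again more regions had higher than lower counts with 1,25D, 813 against 137. In simulated data, 84.8% of 4-fold rises and 18.2% of 4-fold falls were recovered at 4 h. In a separate fit of only the 1478 regions with a mean of at least 20 counts the split was 366 and 294. The median log2 fold change of the higher regions was 1.78, and 58 rose at least 8-fold. Among regions with a mean of at least 20 counts, LSM3 showed the largest rise, from 1.02 ± 0.604 to 19.0 ± 8.85 CPM (SD, n = 3 each). FBP1, which encodes an enzyme of glucose synthesis, rose from 2.28 ± 2.47 to 27.7 ± 1.45 CPM at a region 11812 bp from the gene (SD, n = 3 each; chromosome 9, 94651751 to 94652400).

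By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 4.44 ± 0.53 at LSM3 (SE, adjusted p = 2.3e-10) and 3.97 ± 0.49 at FBP1 (adjusted p = 4.8e-10). SERPINB10, a protease inhibitor gene, rose by 4.40 ± 0.43, and ACOXL, related to acyl-CoA oxidases, by 3.87 ± 0.35 at a region inside the gene. SEMA4D, a semaphorin, rose by 3.7 ± 0.41, SPRY4 by 3.66 ± 0.49 and IGFBP7 by 3.56 ± 0.45. EFL1 (3.52 ± 0.48), LGMN (3.49 ± 0.51), a lysosomal protease gene, and CUX1 (3.45 ± 0.48), a homeobox gene 81882 bp from its region, followed. The chromosome 1 site with no gene within 100 kb rose by 3.38 ± 0.26. Other high-count rises were at NXT1 (2.15 ± 0.26), a chromosome 6 site with no gene nearby (1.60 ± 0.24), CAP1 (0.86 ± 0.23, in the dense stretch) and TNR (0.72 ± 0.24). The call at CAP1 was lost without solvent 4 h replicate 1. At TNR it was lost in 5 fits that left out 1 library, those without solvent 40 min replicate 1, solvent 4 h replicate 1 or 3, 1,25D 40 min replicate 1 or 1,25D 4 h replicate 3. The direction at TNR turned to -2.22 when the window with the smallest p stood for the region. Without 1,25D 4 h replicate 3, 500 of 10176 tested regions were higher.

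The 137 regions lower at 4 h had a median log2 fold change of -1.81, and 57 of them (41.6%) lay in the stretch. PDE4DIP, a centrosome and Golgi protein gene, showed the largest named fall, outside the stretch (-2.31 ± 0.38, SE; edgeR, adjusted p = 1.83e-06). It went from 24.2 ± 1.58 to 4.90 ± 0.827 CPM (SD, n = 3 each). PDE4DIP has near-identical copies on the same chromosome, so its counts are uncertain. ERMAP (-1.33 ± 0.44), a second PPT1 region (-1.33 ± 0.36), COL9A2 (-1.30 ± 0.35) and CITED4 (-1.24 ± 0.33) lay in the stretch, and their calls were lost when libraries were scaled to it. ERMAP and PPT1 were also lost without 1,25D 4 h replicate 2, and COL9A2 and CITED4 without 1,25D 4 h replicate 3. With that scaling the split was 1596 higher and 20 lower. In fits without 1 library, the number of lower calls ranged from 23 without 1,25D 4 h replicate 2 to 230 without solvent 40 min replicate 2.

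**Figure D2:**
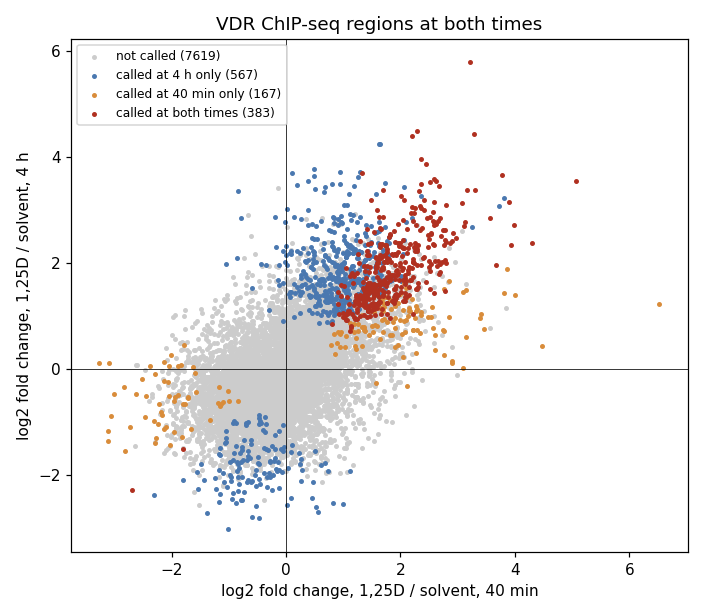
Log2 fold change of 1,25D over solvent at 40 min (horizontal axis) and 4 h (vertical axis) for the 8736 tested regions, 1 point per region, coloured by the time at which it was called. Regions called higher at both times, 381 of them, lie in the upper right, and the correlation across regions, which are not independent replicates, was 0.61.

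Genes of the list of monocyte vitamin D targets were called higher more often than other genes. Of 26 genes with a tested region, 11 were higher at 40 min and 14 at 4 h, while 15 and 12 were not called and none was lower. Here and in the other lists each gene counted by its representing region alone, so another region of an uncalled gene could be higher. Against all genes with a tested region, 348 of 3701 (9.40%) were higher at 40 min and 533 (14.4%) at 4 h. ASAP2, a regulator of membrane traffic, had a log2 fold change of 2.79 ± 0.29 at 40 min and 3.10 ± 0.29 at 4 h. CD93, a surface receptor of myeloid cells, had 2.35 ± 0.54 and 3.04 ± 0.50 at a region 40451 bp from the gene. NINJ1 had 3.90 ± 0.57 and 3.16 ± 0.46 (SE from the fit of all 12 libraries). The call at CD93 at 40 min was lost without 1,25D 40 min replicate 3. By camera with a preset correlation of 0.01, the list stood above the other genes at both times (adjusted p = 5.46e-06 at 40 min and 4.01e-05 at 4 h, limma on voom values). With an estimated correlation p was 0.029 and 0.0383 before adjustment, and neither call held after it (adjusted p = 0.348 and 0.46). Adjusted over the list alone, 14 genes were higher at each time.

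CYP24A1, the enzyme that breaks down 1,25D, and CD14, the monocyte co-receptor for bacterial lipopolysaccharide, were called at 4 h. At a region 27463 bp from the gene, CYP24A1 had a log2 fold change of 2.19 ± 0.46 at 4 h (edgeR, adjusted p = 0.00022) and 1.23 ± 0.51 at 40 min (edgeR, adjusted p = 0.143). CD14 had 1.70 ± 0.51 at 4 h (edgeR, adjusted p = 0.017) and 0.65 ± 0.59 at 40 min (edgeR, adjusted p = 0.593), and its call was lost without solvent 4 h replicate 3 and without 1,25D 4 h replicate 2 or 3. The differences between the times, 0.95 ± 0.70 and 1.05 ± 0.79, were not called. CAMP, which encodes the antimicrobial peptide cathelicidin, had many counts in every group and log2 fold changes of 0.22 ± 0.23 and -0.33 ± 0.22. LRRC8A (0.21 and 0.10) and CEBPA (0.58 and 0.73) were not called at either time. The region of VDR itself had too few counts to be tested, and no region was assigned to THBD.

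**Figure D3:**
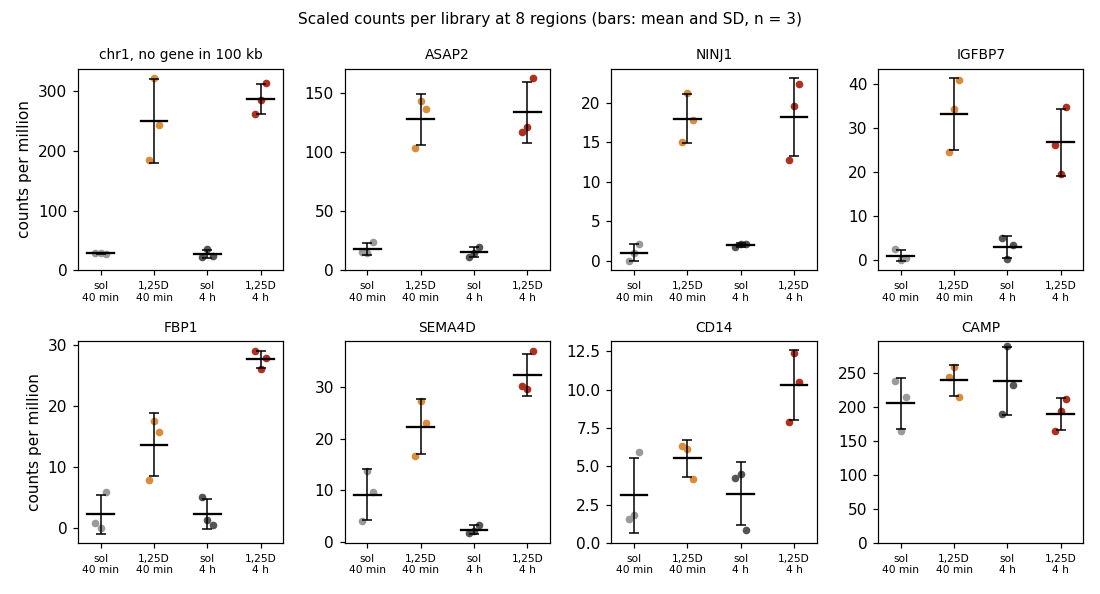
Scaled CPM in each library at 8 regions, with 1 point per library and bars for the mean and SD of 3 libraries; each panel has its own linear axis. The 3 libraries with 1,25D lay above the 3 solvent libraries of the same time at the chromosome 1 site, ASAP2, NINJ1, IGFBP7, FBP1 and SEMA4D, while at CAMP they overlapped.

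In the list of sugar and lipid metabolism, 3 of 11 genes were higher at 40 min and 4 of 11 at 4 h. FBP1, PFKFB4 and SLC37A2, a sugar phosphate transporter gene, were higher at both times. The call at FBP1 at 40 min was lost with DESeq2 and with replicates 1 and 3 only. PFKFB4, whose enzyme sets the level of a glycolysis regulator, had log2 fold changes of 1.49 ± 0.44 and 3.19 ± 0.42. TXNIP, an inhibitor of glucose uptake, was called at 4 h (2.17 ± 0.68), a call lost without solvent 4 h replicate 2 or 3 or 1,25D 4 h replicate 3. The list was not called by camera (adjusted p = 0.182 at 40 min and 0.429 at 4 h, limma). With all regions of each gene it was called in the other direction, down, at 40 min (camera, limma, adjusted p = 0.00855), where SLC2A1 alone gave 57 regions, all in the dense stretch. Among transcription factors under vitamin D, 1 of 13 genes was higher at 40 min and 3 of 13 at 4 h. IRF8 was not among them, but 1 of its 7 tested regions, not the representing one, was higher at each time. BCL6, a repressor of transcription, had log2 fold changes of 1.67 ± 0.34 and 2.37 ± 0.31 at a region 66307 bp from the gene. NFE2, a factor of blood cell development, had 0.81 ± 0.41 (not called) and 2.87 ± 0.42. SPI1, which encodes the myeloid factor PU.1, had 1.45 ± 0.50 at 4 h, a call lost in 5 fits without 1 library (solvent 40 min replicate 1, solvent 4 h replicates 2 and 3, 1,25D 4 h replicates 1 and 3).

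In the innate immune list, 2 of 6 genes were higher at 40 min and 3 of 6 at 4 h. NOD1, a sensor of bacterial cell walls, had log2 fold changes of 2.23 ± 0.59 and 2.96 ± 0.59, and TREM1, an activating receptor of myeloid cells, had 1.62 ± 0.42 and 1.26 ± 0.37. In the vitamin D metabolism list, 1 of 4 genes was higher at 40 min and 2 of 4 at 4 h, with CYP27A1 (1.69 ± 0.52 and 2.88 ± 0.56) and, at 4 h, CYP24A1. In the calcium and bone list, 1 of 8 and 2 of 8 were higher. CALB1, a calcium-binding protein gene, had 1.28 ± 0.39 and 2.00 ± 0.34. ATP2B1, a calcium pump gene 47859 bp from its region, had 1.32 ± 0.40 at 4 h. By representing region, CCL22 (1.39 ± 0.40 and 1.45 ± 0.36) was the 1 of 6 cytokine and chemokine genes called at each time. Of 2 tested regions of CXCL8, 1 was also higher at each time, though not the representing one. CCND2, 60187 bp from its region (2.52 ± 0.73 and 1.52 ± 0.48), was the 1 of 7 cell cycle genes called at each time. At 40 min the calls at NOD1, TREM1, CYP27A1, CALB1, CCL22, CCND2 and PFKFB4 were each lost without solvent 40 min replicate 1 or 2. At 4 h those at TREM1, CCND2 and ATP2B1 were lost without solvent 4 h replicate 3. No gene was called among 1 for antigen presentation, 3 housekeeping genes, 2 lymphocyte markers and 2 liver and neuron markers. By camera, adjusted p ranged upward from 0.182 at 40 min and 0.429 at 4 h over the 11 lists other than the monocyte targets. For calcium and bone and for antigen presentation at 40 min, and for the cell cycle and housekeeping lists at 4 h, the camera direction was down while the median was above 0. Camera compares a list with the other genes, and the median over all 3701 genes was 0.28 at 40 min and 0.27 at 4 h. The calcium and bone (0.26) and housekeeping (0.13) medians lay below it. Those of antigen presentation (0.38) and cell cycle (0.32) lay above it.

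**Figure D4:**
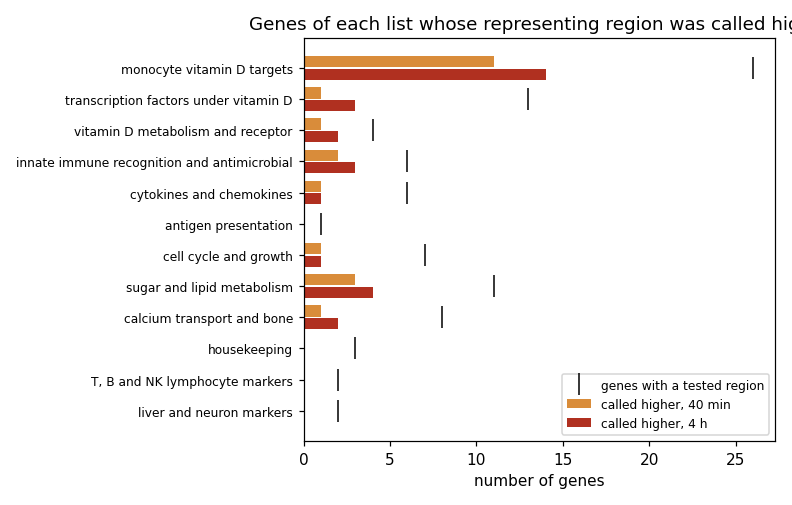
Number of genes in each of 12 lists whose representing region was called higher at 40 min and at 4 h (bars), with the number of genes that had a tested region (tick). Monocyte vitamin D targets had 11 and 14 of 26 genes higher.

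The third comparison asked whether the 1,25D effect differed between the times. It was not shown to differ at any region: edgeR's quasi-likelihood test called 0 regions, with 383 at an unadjusted p under 0.05 where chance gives 436.8, and DESeq2 called 0 with 320. Among named regions, p was smallest at SEMA4D (2.38 ± 0.58), SERPINB10 (2.20 ± 0.63) and NFE2 (2.06 ± 0.60), each larger at 4 h. Their adjusted p was 0.62, 0.874 and 0.874 (edgeR, Benjamini-Hochberg). From 40 min to 4 h their solvent levels changed by a log2 fold change of -1.86, -1.46 and -1.26. Their 1,25D levels changed by 0.51, 0.73 and 0.80, and none of these changes was called. At SERPINB10, solvent 40 min replicate 2 had 12.9 CPM, against 1.58 in replicate 1 and 3.78 in replicate 3. The comparison had little power: in simulated data, 12.1% of regions whose effect was 4-fold larger at 4 h and 3.03% of those 4-fold smaller were recovered. These were 4 of 33 and 1 of 33 regions in a single simulated data set. Without solvent 4 h replicate 3, 2 regions were called. None of the 12 gene lists was called for this comparison by camera (limma, smallest adjusted p = 0.124).

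Of the 492 regions higher at 40 min, 381 (77.4%) were also higher at 4 h, where independent lists would share 45.8. The times used different solvent libraries. Of the 432 regions called higher at 4 h and not at 40 min, 414 had a positive log2 fold change at 40 min (median 0.95). Lower calls were shared at 2 regions, where independent lists would share 0.91. Of the 135 regions called lower at 4 h and not at 40 min, 114 had a negative log2 fold change at 40 min (median -0.55). Of all 137 lower regions at 4 h, 57 lay in the dense stretch. Its 1067 tested regions, called or not, had a median of -0.59 at 40 min. Without solvent 40 min replicate 1, 237 regions were higher at both times.

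Time by itself gave no calls. Between the solvent groups edgeR called 0 regions, with 439 at an unadjusted p under 0.05, and DESeq2 called 0 with 362. Between the 1,25D groups edgeR called 0, with 277 at an unadjusted p under 0.05, and DESeq2 called 0 with 214. At SEMA4D the solvent level was 9.16 ± 4.95 at 40 min and 2.38 ± 0.845 CPM at 4 h (SD, n = 3 each). Without solvent 4 h replicate 3, 2 regions were called between the solvent groups, and without 1,25D 40 min replicate 3, 1 was called between the 1,25D groups.

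The last comparison asked whether regions called higher with 1,25D lay near gene ends. At 4 h, 34 of 813 higher regions (4.18%) lay within 1 kb of the end of a protein-coding gene, against 5.97% of regions not called (odds ratio 0.687, Fisher's exact test, two-sided p = 0.04). At 40 min it was 5.28% against 5.81% (odds ratio 0.904, Fisher's exact test, two-sided p = 0.691). Within 5 kb the odds ratio at 4 h was 0.725 (Fisher's exact test, p = 0.00179). These tests were not adjusted for each other, and the call at 1 kb was lost under several settings and in 8 of the 12 fits without 1 library, most of all without 1,25D 4 h replicate 1 (odds ratio 0.8125). Inside genes lay 46.4% of higher regions at 4 h and 49.4% of regions not called.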

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

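The alternatives chosen after seeing the data were scaling to the dense stretch of chromosome 1, leaving the stretch out, Simes' method over all windows, a merging gap of 500 bp, replicates 1 and 3 only, and thinning; the others were planned. Higher calls outnumbered lower calls under every setting run. The counts of higher regions stayed within 1.5 times the main ones (492 at 40 min, 813 at 4 h) except as follows and in 2 fits without 1 library. These 2 fits gave 299 at 40 min without solvent 40 min replicate 1 and 500 at 4 h without 1,25D 4 h replicate 3. With a mean of at least 20 counts, 260 and 366 regions were higher, 205 and 294 were lower and 217 were higher at both times, of 1478 tested. With an adjusted p below 0.01 the values were 292 and 495 higher, 11 and 25 lower and 227 at both times. Against a 1.5-fold change they were 251 and 476 higher, 11 and 34 lower and 188 at both times. With scaling to the stretch they were 1163 and 1596 higher, 12 and 20 lower and 899 at both times; this moved the median log2 fold change of all regions to 0.45 and 0.40, from -0.02 and -0.07. With replicates 1 and 3 only, 301 regions were higher and 32 lower at 40 min, and 237 higher at both times.

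Lower calls moved most. At 40 min there were 18 with total counts only, 26 with scaling to regions with lower counts, 17 with no filter, 171 with only the groups compared and 11 with Simes' method. The numbers of regions tested differed: 19169 with no filter, 2935 with only the groups compared and 9529 with Simes' method, against 8736. At 4 h there were 74 with total counts only, 66 with scaling to regions with lower counts, 88 with no filter and 25 with Simes' method. The cause was not tested. Thinning the 4 h libraries gave medians of 610 higher and 202.5 lower.

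Leaving out each library in turn gave 299 to 532 higher and 14 to 74 lower regions at 40 min, 500 to 890 higher and 23 to 230 lower at 4 h, and 237 to 380 at both times. It gave 0 to 2 regions for the change of the effect with time, 0 to 2 between solvent groups and 0 to 1 between 1,25D groups. The fits without 1 library tested 9518 to 12866 regions, against 8736. Dependence on a library cannot be told apart here from the changed filter. With only the groups compared, 3 regions were called between the 1,25D groups.

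The labels do not say whether a replicate number marks a shared culture or day. Correlations of deviations between libraries with the same number were low, 0.038 to 0.124. Even so, all 12 libraries correlated best with their own number, at most a hint of pairing from the data and not the design. Replicate 1 had the lowest total count in every group, so the number also went with depth, and the 2 cannot be told apart here. With the replicate number as a block, 555 and 929 regions were higher and 88 and 211 lower. The odds ratio of lying within 1 kb of a gene end at 4 h was then 0.723 and no longer past the threshold (Fisher's exact test, p = 0.0535).

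That odds ratio at 4 h was past the threshold as tested and was also lost with RLE (0.717), total counts (0.737), scaling to regions with lower counts (0.770), adjusted p below 0.01 (0.638), 1.5-fold (0.702), scaling to the stretch (0.873), Simes' method (0.801) and replicates 1 and 3 only (0.738). Without 1 library it ranged from 0.603 to 0.8125. At 40 min it passed the threshold with no filter (0.532), a mean of at least 20 counts (0.437) and only the groups compared (0.597). The cause was not tested.

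Of the lists, 1 was called at each time. With an estimated correlation 0 were called at both, and with fry, which does not compare a list with other genes, 2 and 8. With all regions of a gene 4 and 2 were called, and with the region nearest the gene 2 at 40 min. With all regions of a gene the sugar and lipid list turned from up to down at 40 min (adjusted p = 0.00855, camera, limma), with 57 regions from SLC2A1 in the stretch, and the TNR region turned to a log2 fold change of -2.22 at 4 h with Simes' method. Of 38 named regions higher at 4 h, 30 were called in all fits without 1 library, as were 21 of 34 at 40 min. Of the named falls these were 1 of 5 at 4 h (PDE4DIP) and 0 of 5 at 40 min. The share of VDR response elements was not run. In simulated data 15.2% of 4-fold falls and 66.7% of 4-fold rises at 40 min were recovered.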

Other observations

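Chromosome 1 held 35.9% of the tested regions but 14.6% of those higher at 40 min and 12.4% of those higher at 4 h. It held 44 of the 58 lower regions at 40 min (75.9%) and 95 of the 137 at 4 h (69.3%). Of these, 18 and 38 lay outside the dense stretch. How many of them lay in the closely spaced part toward the end of chromosome 1 was not counted. Several genes had more than 1 region called higher: CD93 had 3 of its 4 tested regions higher at 4 h, FBP1 had 3 of 3 and CYP24A1 had 2 of 4. Scaled to the stretch, 20 regions were lower at 4 h, among them 4 at HIVEP3 and 2 at ESRRG, genes named after their values were seen; the 4 at HIVEP3 lay in the stretch.

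The tests below were written before their results were seen, except the test of a lower background share. The first pattern is the regions called lower with 1,25D, with a lower share of background counts in the 1,25D libraries as a candidate explanation. When libraries were scaled to the stretch, 20 of the 137 lower regions at 4 h stayed lower (14.6%, exact 95% interval 9.15 to 21.6). This scaling raises all regions alike, so calls are lost in any case, and the 137 kept a median log2 fold change of -1.35 (from -1.81); the explanation stays open. For the 20 that stayed, chance or background in the 4 h libraries alone cannot be told apart from a fall: 15 had a negative log2 fold change in the separate 40 min libraries (75%, exact 95% interval 50.9 to 91.3), while 30.2% of all regions did. The bound written beforehand counted 75% or more against this explanation; reading it with an interval was decided after the result was seen.

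The second pattern is the larger number of regions called higher at 4 h, 813 against 492. With the 4 h libraries thinned to the 40 min totals, a median of 610 regions was higher over 20 draws (585 to 652). That is 1.24 times the 40 min count, between the 2 bounds set beforehand, while lower calls went from 137 to a median of 202.5, so the part of depth stays open. A larger 1,25D effect at 4 h was tested over 1302 regions higher on the average of both times, whose effect changed by a median of 0.08 (rotation test fry, n = 12 libraries, p = 0.488; 0.736 under scaling to the stretch). The bound set beforehand would have counted a p of 0.05 or more against this explanation; this reading was changed after the result was seen, because a missed threshold excludes nothing, and the explanation stays open.

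The third pattern is the dense stretch itself. VDR binding along all of it was tested through the share of regions higher at 4 h. This was 0.7498% (8 of 1067) against 10.5% elsewhere (Fisher's exact test, two-sided p = 9.33e-37, with neighbouring regions taken as independent). Few stretch regions thus rose with 1,25D. Binding that was alike in solvent and 1,25D would also give few higher calls, and the stretch as a whole had a median log2 fold change of -0.59. The test therefore cannot decide whether VDR was bound there. Extra copies of the stretch may account for its coverage, but the 90th percentile of mean solvent counts per window over its 79 bins was 3.24 times the 10th, between the bounds of 2 and 4 set beforehand, so this cannot be told apart from another source of uneven background.

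For the 40 min and the 4 h comparison, 1 of the 10 splits of the 6 libraries gave as many regions, the real one, with 550 and 950 called against at most 0 in the other splits; 10 splits are too few for a share under 0.05. Between the solvent groups and between the 1,25D groups 0 regions were called, so all 10 splits gave as many by construction (at most 7). For the change of the effect with time 0 were called, and all 100 drawn splits likewise gave as many (at most 16). These last splits therefore test nothing.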
